A study of Mus musculus with 24 samples.

How the data were processed

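Messenger RNA was sequenced from T cells of OT-1 mice, whose CD8 T cells carry a transgenic receptor for an ovalbumin peptide. Per the labels' protocols, splenocytes were cultured with peptide at 2 µg/mL, Toll-like receptor (TLR) agonists were added 1 h before the peptide, T cells were taken by immunomagnetic negative selection, and libraries were made with a stranded poly-A kit. The strand setting used in counting is not given in the sources used here, so genes that overlap or run antisense to another gene are uncertain. Genes of families with near-identical copies, among the named ones Gbp6, Ifi27l2a, Lilr4b, Pydc3, Slfn8 and the H2 genes, are uncertain where the counting could split their reads.

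The authors deposited expected counts per gene, 1 file per library, not scaled between libraries. Per the submitters' processing notes, the tools were STAR (an aligner), RSEM (which estimates counts of reads shared between transcripts) and edgeR, on build GRCm38. Their versions, their roles and the annotation release are not given in the sources used here. That the values are expected counts was taken from the deposited files themselves, in which 28.7% of the values above 0 are not whole numbers and the totals differ between libraries. The files hold 48526 genes with an Ensembl ID and a symbol each, and 0 of them name no gene. Of the IDs, 48144 have coordinates in GENCODE M21, on GRCm38, from which positions are given. The 249 symbols that several IDs share were kept apart by ID.

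The labels give 6 groups of 4 libraries, named by agent (OVA, the peptide alone; TLR2; TLR7) and time (24 h or 72 h). Replicate numbers came from the same labels. The labels do not say whether replicates came from separate mice, cultures or RNA samples, so p-values measure the spread between these samples, which may be technical. Expected counts were rounded to whole numbers. CPM, counts scaled to library size, were computed from the deposited counts with TMM-scaled library sizes, and log2 CPM with a prior count of 2. Totals ran from 10.5 to 27.1 M (mega) counts per library, so a count of 3 corresponds to 0.286 CPM in the shallowest and 0.111 CPM in the deepest. These floors cover counting error only.

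Each comparison was tested with edgeR's quasi-likelihood F test after TMM normalization and filterByExpr (minimum count 10, minimum total 15), which kept 14560 genes. All 24 libraries entered 1 model with a term per group and 18 residual degrees of freedom. Benjamini-Hochberg adjustment ran over the genes tested, with a threshold of 0.05 on the adjusted p, and calls with an absolute log2 fold change of at least 1 were also counted. There were 7 comparisons of 2 groups and 2 differences between times, each the agonist effect at 72 h minus that at 24 h. The common biological coefficient of variation was 0.321.

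There were 36 gene lists. They covered inhibitory and costimulatory receptors, cytotoxic effectors, T cell cytokines, type I interferon, interferon-gamma, IL-12 and STAT4, NF-kB targets, the early T cell receptor (TCR) response, effector and exhaustion transcription factors, naive and memory genes, homing receptors, cytokine receptors and the TLR pathway. Further lists covered G1/S, G2/M, glycolysis, hypoxia, oxidative phosphorylation, cholesterol synthesis, ATF4 and amino acids, endoplasmic reticulum (ER) stress, p53 and apoptosis, ribosome biogenesis and CD8 T cells. Lists of other cell types covered CD4 and regulatory T cells, B cells, plasma cells, macrophages and monocytes, dendritic cells, neutrophils, erythroid cells, NK cells, mast cells and basophils, platelets and megakaryocytes, and stromal and endothelial cells. Of their 759 symbols, 749 are in the files. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether a list's genes move 1 way on balance, were alternatives. Sums of CPM over the markers of other cell types were compared with 2-sided exact permutation tests of 4 against 4 libraries, which have 70 arrangements and a smallest p of 0.0286.

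Groups, tests, lists, alternatives and the naming rule were set before the data were examined. The rule named Pdcd1 everywhere. It named up to 8 rises and 8 falls per comparison with the largest log2 fold changes among genes past the threshold, with a mean of at least 5 CPM in either group and no overlap between the libraries of the groups; predicted genes and receptor segments were left out. It named up to 3 members past the threshold for each list past its test and for 5 fixed lists, and 5 rises and 5 falls per difference between times. The text gives a part of these, and other list members with values only; some named by the rule are not reported here.

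The alternatives were RLE scaling, no scaling beyond library size, no filter on low counts, a stricter filter, the replicate number as a block, robust empirical Bayes, a fit on only the groups compared, DESeq2, and leaving out each library in turn. After the data were seen, 3 were added. These leave out the 5 libraries of under 12 M counts, leave out 8 libraries in the middle of the first principal component, or use the first component of the within-group deviations (40.5% of the within-group variance) as a covariate. The 8 were picked on their expression, which makes this a check on the comparisons and not a regrouping of samples. It leaves TLR2 at 72 h with 1 library, assumed to vary like the other groups. The covariate is taken from the deviations of the same libraries, so it lowers the residual spread by construction. A higher count of calls with it is no evidence of more changed genes. Replicates of a group differed beyond sampling noise, with a chi-square per degree of freedom between 4.58 and 253, so no library was counted as a duplicate.

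On simulated counts for the 14560 genes, with 100 genes changed at each fold size, the test recovered 34% of 2-fold and 80% of 4-fold changes for TLR2 against OVA at 24 h, and 40% and 79% for TLR7 at 24 h. At 72 h it recovered 49% and 79% for TLR2, and 34% and 77% for TLR7. False calls numbered 8 in each comparison at 24 h and 3 in each at 72 h. The simulated genes varied independently of each other, with no axis of variation shared within groups and no libraries between the times. These rates therefore do not carry over to the real libraries. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.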

Results

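Gene expression was measured in T cells, given in the labels as CD8 T cells, that were isolated by negative selection from splenocyte cultures of OT-1 mice. The cultures were activated with ovalbumin peptide alone (OVA), or with peptide plus an agonist of TLR2, a receptor for bacterial lipoproteins, or of TLR7, a receptor for single-stranded RNA. Cells were taken at 24 h or 72 h, giving 6 groups of 4 libraries. The labels name the agonist groups only TLR2 and TLR7. Of the agonists they list, Pam3CSK4 (300 ng/mL) acts on TLR2, and gardiquimod (3 µg/mL) and R848 (10 µg/mL) both act on TLR7. Which of these was used in the sequenced TLR7 groups is not stated in the labels. The study asks how TLR agonists present during activation change T cells, with attention to PD-1. Library totals ran from 10.5 to 27.1 M counts. In 5 libraries they were low, at 11.1 M in OVA 24 h replicate 4, 11.6 M in TLR2 24 h replicate 4, 10.9 M in TLR7 24 h replicate 2, and 10.5 and 11.7 M in TLR7 72 h replicates 1 and 2. The others held 21.5 to 27.1 M. Of 48526 genes, 14560 were tested.

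The first principal component held 60.2% of the variance and followed time, but 8 libraries lay between the others. Of the remaining 16, those taken at 24 h scored 85.2 to 99.1 and those taken at 72 h scored -90.5 to -56.5, whereas the 8 scored -20.5 to -1.2. They were OVA 24 h replicates 1 and 3, TLR7 24 h replicates 3 and 4, OVA 72 h replicate 4, and TLR2 72 h replicates 1, 3 and 4. TLR2 at 24 h and TLR7 at 72 h held 0 such libraries. Over 9690 genes, each of the 8 was matched by a weighted sum of a 24 h and a 72 h library, with a weight of 0.46 to 0.56 on the 24 h library. The misfit of that sum was 6.96 to 26.3 (chi-square per degree of freedom), against 286 to 417 for the best single library, or 2.4% to 7.8% of it. For the other 16 libraries the best sum left 41.7% to 96.6% of the misfit, and 0 of them met the same criterion. Of the 8, 3 (the OVA ones) were matched by libraries of their own agent and 5 by a pair that held a library of another agent, and TLR7 24 h replicate 4 and TLR2 72 h replicate 4 were matched by the same pair. Only the other 16 libraries could serve as the single library or form a pair, among them 1 of TLR2 at 72 h and 2 of TLR7 at 24 h. A middle library could thus not be matched by another middle library, which raises the single misfit of the 8 by construction. Middle libraries of the same group differed from each other by 11.9 to 22.8 (chi-square per degree of freedom over a different set of genes). The share of 2.4% to 7.8% is therefore partly fixed by that rule. The 8 held 22.7 to 27.1 M counts, so none was shallow. Because they fall unevenly on the groups, values without them are given with the gene lists; that choice was made after the data were seen.

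**Figure D1:**
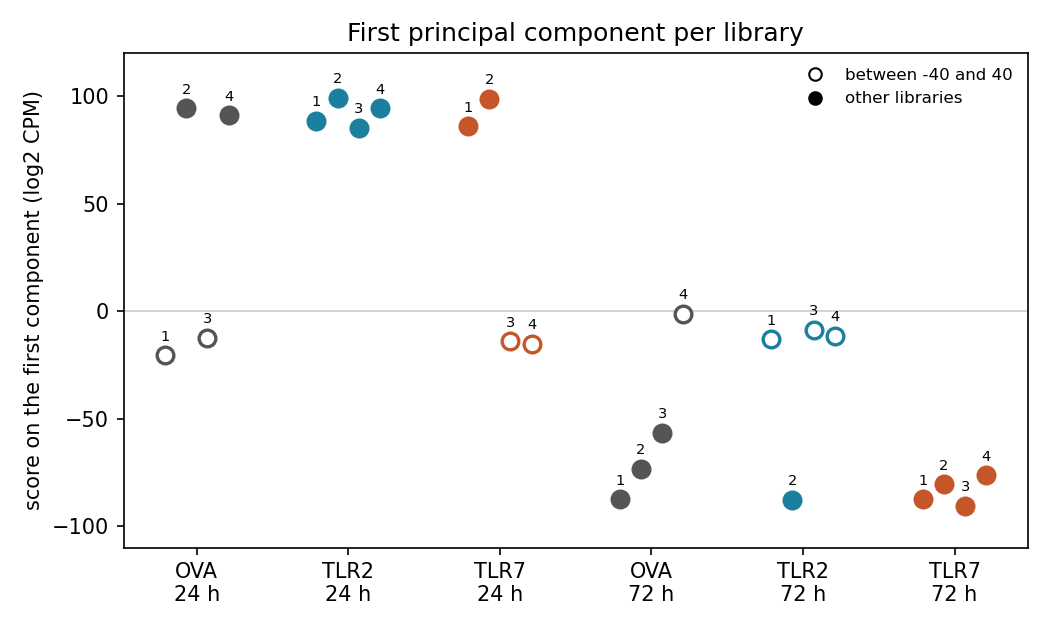
Score of each library on the first principal component of log2 CPM (vertical axis, log2 CPM) by group (horizontal axis, 4 libraries each); open points are the libraries between -40 and 40. The 8 open points score -20.5 to -1.2, and the remaining libraries lie at or above 85.2 (24 h) or at or below -56.5 (72 h).

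**Figure D2:**
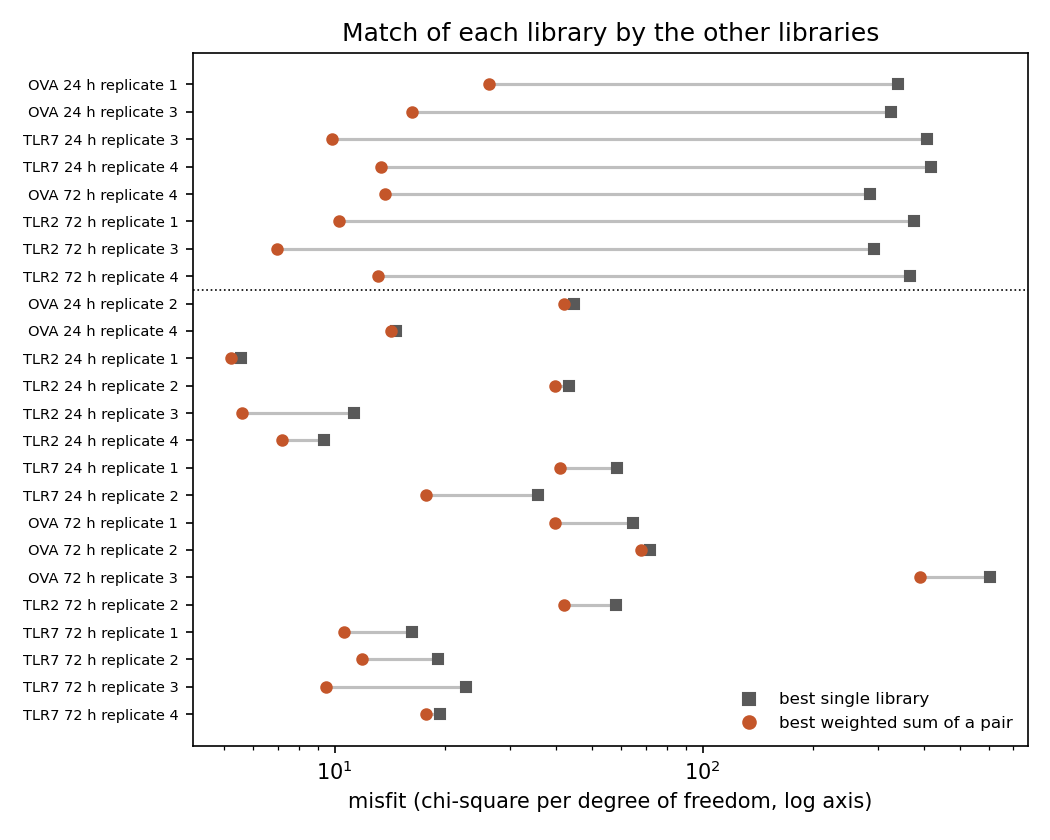
Misfit of each library (chi-square per degree of freedom over 9690 genes, log axis) to the best single library (squares) and to the best weighted sum of a pair (circles). Only the 16 libraries outside the middle could serve as the single library or in the pair. In the 8 middle libraries the sum leaves 2.4% to 7.8% of the single-library misfit, and in the other 16 it leaves 41.7% to 96.6%.

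Pdcd1, which encodes the inhibitory receptor PD-1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553, GRCm38), fell with the TLR7 agonist at 72 h. Its level was 39.6 ± 15.7 CPM against 166 ± 37.3 CPM with OVA (SD, n = 4 each), a log2 fold change of -2.06 (SE 0.43, edgeR adjusted p = 0.00999). Every TLR7 library (20.9 to 57.5 CPM) lay below every OVA library (123 to 203 CPM). With the TLR2 agonist at 72 h Pdcd1 stood at 73.4 ± 20.3 CPM, a log2 fold change of -1.17 (SE 0.41) that did not pass (adjusted p = 0.334). Every TLR2 library at 72 h (60 to 104 CPM) also lay below every OVA library, and 3 of these TLR2 libraries were among the 8 middle ones. At 24 h Pdcd1 stood at 92.9 ± 22.9 CPM with OVA, 66.6 ± 25.1 CPM with TLR2 (adjusted p = 0.545) and 64.9 ± 54.2 CPM with TLR7 (-0.51, adjusted p = 0.776). The TLR7 libraries at 24 h spread from 28.3 to 144 CPM, the highest being replicate 3, 1 of the 8 middle libraries, without which the log2 fold change against OVA was -1.26 (adjusted p = 0.0918). The TLR7 response did not pass as different between the times (-1.55, SE 0.58, adjusted p = 0.188, 0.126 to 0.908 over the alternatives); this difference was -0.75 without TLR7 24 h replicate 3 and -0.18 without the 8. OVA at 72 h against 24 h did not pass (0.84, adjusted p = 0.131). TLR7 against TLR2 at 72 h did not pass either (-0.89, adjusted p = 0.177), but did in the fit on these groups alone (-0.91, adjusted p = 0.0438), with a range of 0.0438 to 0.646 over the alternatives. Without the 8 libraries the TLR7 log2 fold change was -1.93 at 72 h (adjusted p = 0.0121) and -1.75 at 24 h (adjusted p = 0.0498). Across all alternatives, leave-outs included, the adjusted p at 72 h ran from 1.23e-04 to 0.334 and that at 24 h from 0.0498 to 1. The call at 72 h ended without the 5 shallow libraries (-1.68, adjusted p = 0.334), without TLR7 replicate 1 (-1.80, adjusted p = 0.0668) and without TLR7 replicate 2 (adjusted p = 0.051).

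**Figure D3:**
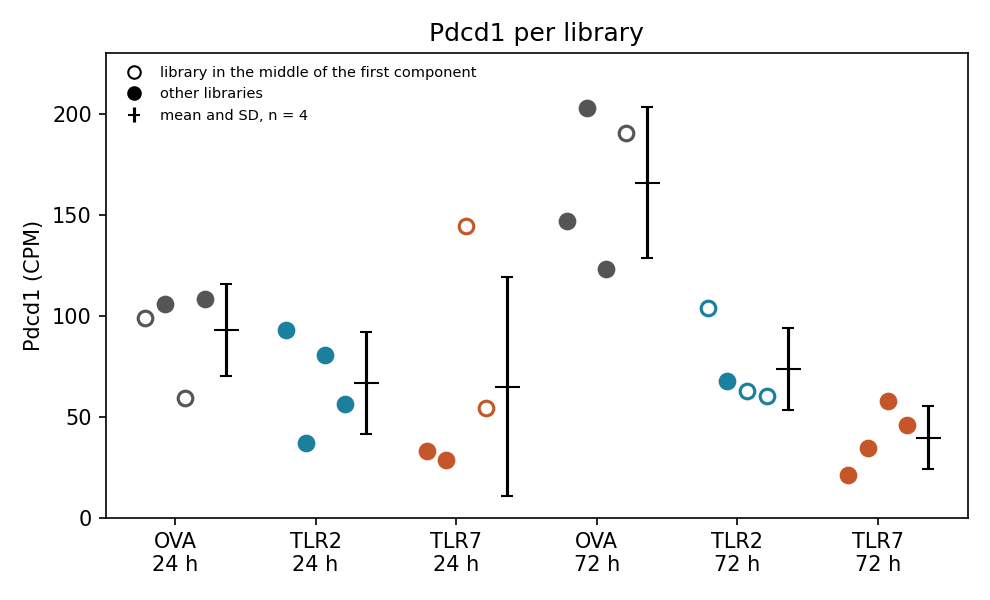
Pdcd1 level (vertical axis, CPM) in each library by group (horizontal axis), with the mean and SD (n = 4) as bars and the middle libraries as open points. At 72 h the 4 TLR7 libraries lie at 20.9 to 57.5 CPM and the 4 TLR2 libraries at 60 to 104 CPM, both under the 4 OVA libraries at 123 to 203 CPM.

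With the TLR7 agonist at 24 h, the cytokine genes Il21 and Tnf rose and genes of B cells such as Cd79b fell against OVA. Il21, an interleukin made by activated T cells (ENSMUSG00000027718, chromosome 3, 37222759 to 37232636), rose from 2.43 ± 2.91 to 132 ± 71.1 CPM (n = 4 each), a log2 fold change of 5.69 (SE 1.19, edgeR adjusted p = 0.0461). Tnf, an inflammatory cytokine, rose from 13.2 ± 3.29 to 33.6 ± 9.60 CPM (1.34, SE 0.28, adjusted p = 0.0483). Sema7a, a membrane-anchored semaphorin, and Nfkbiz, a regulator of NF-kB induced by TLR signals, rose by 2.12 (SE 0.39) and 1.44 (SE 0.27). Cd79b, a signalling chain of the B cell receptor, fell from 26.0 ± 13.1 to 4.94 ± 0.667 CPM (-2.39, SE 0.43, adjusted p = 0.0283). Fcmr, the receptor for IgM, fell from 13.4 ± 4.28 to 0.578 ± 0.461 CPM, and Fcer2a, the IgE receptor CD23, from 9.16 ± 5.48 to 0.0874 ± 0.0944 CPM. Tox2, an HMG-box factor of activated T cells, rose from 0.0842 ± 0.0604 to 1.86 ± 0.998 CPM. The type I interferon list was higher, with a median log2 fold change of 0.77 over 37 genes, 32 of them positive (adjusted p = 1.22e-14 with the preset correlation; adjusted p = 0.246 with an estimated correlation). Only 1 of these genes passed over all genes tested, Slfn8, and 10 passed adjusted over the list alone. The lists of IL-12 and STAT4 (0.52), effector and exhaustion transcription factors (0.59) and interferon-gamma (0.34) were also higher, and 6, 7 and 7 of their genes were higher adjusted over the list alone (adjusted p = 0.0965 with an estimated correlation for each). The G1/S list was lower (median -0.61, all 30 genes negative, 0 called, 7 lower adjusted over the list alone; adjusted p = 0.443 with an estimated correlation), and so was the G2/M list (-0.38, 0 called, 4 of 32; adjusted p = 0.452). B cell markers were lower as a list (median -1.66), with 20 of 20 negative, 3 called and 11 adjusted over the list alone (adjusted p = 0.0965 with an estimated correlation). OVA and TLR7 at 24 h each held 2 middle libraries, and without the 8 the medians were 1.40 for type I interferon, 1.62 for IL-12 and STAT4, 1.02 for the transcription factors, 0.50 for interferon-gamma, -0.64 for G1/S, -1.39 for G2/M and -2.20 for B cells.

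Further lists of TLR7 against OVA at 24 h passed with the preset correlation only. Early TCR response genes (median 0.20, estimated-correlation adjusted p = 0.437), cytotoxic effectors (0.11, adjusted p = 0.452) and cytokine receptors (0.21, adjusted p = 0.503) were higher as lists. CD8 T cell genes (-0.25, adjusted p = 0.452), oxidative phosphorylation (-0.15, adjusted p = 0.772), dendritic cell markers (-0.77, adjusted p = 0.0965) and neutrophil markers (-3.89, adjusted p = 0.582) were lower, the second p being that with an estimated correlation throughout. The T cell cytokine list was called upward (preset adjusted p = 0.0418, 0.452 with an estimated correlation) with a mean of 0.37 although its median was -0.04; Il21 and Tnf were its 2 called genes. Without the 8 the medians were 0.41 for the early TCR response, 0.39 for cytotoxic effectors, which no longer passed, 0.33 for cytokine receptors, -0.59 for CD8 T cells, -0.20 for oxidative phosphorylation, -0.82 for dendritic cells, -3.01 for neutrophils and 1.04 for T cell cytokines. With the covariate the calls of T cell cytokines (-0.11), cytotoxic effectors (0.07) and neutrophils (-2.78) were lost, and without the 5 shallow libraries that of cytotoxic effectors (0.09). In all, 32 genes changed, 22 up and 10 down, 19 and 9 of them by at least 2-fold; 1471 had an unadjusted p under 0.05. DESeq2 called 243, the fit without the 8 libraries 398 (205 up and 193 down), that with the covariate 224, and the fits without the 5 shallow libraries or on these groups alone 0. The count became 0 without OVA replicate 2 or 4 or TLR7 replicate 1 or 2, 3 without OVA replicate 3, 6 without OVA replicate 1 and 146 without TLR7 replicate 3.

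With the TLR2 agonist at 24 h no single gene passed against OVA, and lists passed with the preset correlation only. The type I interferon list was lower, with a median of -0.69 and 34 of 37 genes negative (preset adjusted p = 8.37e-09; adjusted p = 0.711 with an estimated correlation), and 9 genes were lower adjusted over the list alone. G1/S genes (0.39, 28 of 30 positive, preset adjusted p = 3.15e-05) and ribosome biogenesis genes (0.36, 30 of 30 positive, preset adjusted p = 1.28e-04) were higher as lists, with 0 genes adjusted over the list alone in each (adjusted p = 0.711 with an estimated correlation). Genes of ATF4 and amino acid supply were lower (-0.22, 9 adjusted over the list alone, preset adjusted p = 7.99e-04), as were those of hypoxia (-0.44, preset adjusted p = 0.0424), platelet and megakaryocyte markers (-0.98) and CD8 T cell genes (-0.36). The adjusted p = 0.711 with an estimated correlation for these 4 lists too. The OVA group held 2 middle libraries and the TLR2 group 0. Without the 8 the medians were -0.38 for type I interferon, 0.09 for G1/S, 0.00 for ribosome biogenesis, 0.01 for ATF4, 0.35 for hypoxia, -0.74 for platelets and -0.33 for CD8 T cells. T cell cytokines (0.28), cholesterol synthesis (0.14) and ER stress (0.22) were higher and interferon-gamma (-0.20) lower, with an adjusted p = 0.711 with an estimated correlation, and oxidative phosphorylation was higher (0.08), with 0.761; without the 8 these stood at 0.40, 0.05, 0.00, -0.15 and -0.11. Of these 12 lists, ribosome biogenesis, cholesterol synthesis and ER stress no longer passed without the 8, ATF4, hypoxia and oxidative phosphorylation turned, and T cell cytokines, cholesterol synthesis and ER stress no longer passed with the covariate. Without the 5 shallow libraries T cell cytokines (0.41), interferon-gamma (-0.17), oxidative phosphorylation (0.07), cholesterol synthesis (0.20) and ER stress (0.31) did not pass. edgeR called 0 genes, with 2211 at an unadjusted p under 0.05, and DESeq2 called 345. The fit with the covariate, which lowers the residual spread by construction, called 1803 genes, and that without OVA replicate 2 called 546.

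TLR7 against TLR2 at 24 h compares the agonists directly. Interferon genes rose with TLR7: Stat2, a transducer of the type I interferon receptor (ENSMUSG00000040033, chromosome 10, 128270559 to 128292849), from 16.3 ± 2.37 to 52.3 ± 12.3 CPM (n = 4 each), a log2 fold change of 1.68 (SE 0.28, edgeR adjusted p = 0.0171). Zbp1, a nucleic acid sensor, rose from 33.8 ± 8.93 to 108 ± 38.6 CPM (1.68), and Oas3, an antiviral enzyme, from 5.19 ± 3.04 to 44.4 ± 19.8 CPM (3.07, SE 0.64). Of 37 type I interferon genes, 36 were positive, 17 rose and 32 passed adjusted over the list alone, with a median of 1.65 (preset adjusted p = 2.34e-30; adjusted p = 0.0819 with an estimated correlation). The interferon-gamma list was higher by a median of 0.60, with 5 called, among them Gbp6, Nlrc5 and the peptide transporter Tap1, and 17 adjusted over the list alone. This is the only list of all comparisons that kept its call with an estimated correlation (adjusted p = 0.0365). Rrm2, a subunit of ribonucleotide reductase (ENSMUSG00000020649, chromosome 12, 24708241 to 24714146), fell, at 72.6 ± 24.9 against 299 ± 57.4 CPM (-2.04, SE 0.39, adjusted p = 0.0171). So did Tyms, thymidylate synthase, at 30.6 ± 6.97 against 96.4 ± 10.5 CPM, and Mybl2, a cell cycle factor, at 25.8 ± 7.54 against 79.8 ± 11.7 CPM. The G1/S list was lower (median -0.97, 29 of 30 negative, 5 called, 21 adjusted over the list alone), with an adjusted p = 0.294 with an estimated correlation, and so was the G2/M list (-0.35, 4 called, among them Ccna2; estimated-correlation adjusted p = 0.494). Cdkn1a, an inhibitor of cyclin-dependent kinases, rose from 17.2 ± 2.18 to 56.1 ± 20.1 CPM (1.71, SE 0.36), within a p53 and apoptosis list that was higher by 0.14 (estimated-correlation adjusted p = 0.294). Without the 8 the medians were 1.61 for type I interferon, 0.73 for interferon-gamma, -0.74 for G1/S, -1.57 for G2/M and 0.29 for p53.

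TLR7 held 2 middle libraries in this comparison and TLR2 0, and genes with a wide spread in the TLR7 group are affected by that. Vldlr, a lipoprotein receptor, rose to 14.1 ± 15.9 CPM from 0.140 ± 0.0661 CPM (6.56), Trib3, a stress-induced pseudokinase, to 35.8 ± 38.6 from 1.90 ± 0.225 CPM (4.24), and Ddit3, a stress transcription factor, to 26.1 ± 23.7 from 3.38 ± 0.207 CPM (2.96). Without the 8 these log2 fold changes were 1.51, 0.88 and 0.90. The ATF4 list was higher (0.36, 5 called, 11 adjusted over the list alone) and the hypoxia list too (0.83, 0 called, 7 adjusted over the list alone), with an adjusted p = 0.39 and 0.542 with an estimated correlation and medians of 0.17 and -0.17 without the 8. B cell markers were lower as a list (-1.67, 2 called, 8 adjusted over the list alone; adjusted p = 0.294 with an estimated correlation), and stood at -1.27 without the 8. Other lists passed with the preset correlation only. IL-12 and STAT4 (0.58), transcription factors (0.50), cytokine receptors (0.44), cytotoxic effectors (0.35) and platelets (0.94) were higher. Cholesterol synthesis (-0.26), oxidative phosphorylation (-0.21), ER stress (-0.25), ribosome biogenesis (-0.26) and dendritic cells (-0.68) were lower, and over these 10 lists the adjusted p ran from 0.294 to 0.737 with an estimated correlation. Without the 8 these medians were 0.83, 0.46, 0.23, 0.24 and 0.20, and -0.31, -0.10, -0.10, 0.11 and -0.07, ribosome biogenesis having turned. Cytotoxic effectors, platelets, oxidative phosphorylation and ER stress no longer passed. With the covariate or without the 5 shallow libraries cytotoxic effectors, ER stress and dendritic cells did not. There were 180 calls, 92 up and 88 down (70 and 67 by at least 2-fold), against 1016 with DESeq2, 204 without the 8, 2565 with the covariate, 309 on these groups alone and 0 without the 5 shallow libraries. The count became 0 without TLR2 replicate 1 or 4, and 49 and 39 without TLR2 replicates 2 and 3. It was 531, 629, 118 and 31 without TLR7 replicates 1 to 4.

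At 72 h the TLR7 agonist was accompanied by lower levels of many genes against OVA. Some early TCR response genes fell (7 of 26, with 2 higher; adjusted p = 0.375 for the list with an estimated correlation), among them the transcription factor Egr3 (ENSMUSG00000033730, chromosome 14, 70077203 to 70082614), at 0.0862 ± 0.127 against 2.50 ± 1.62 CPM (n = 4 each, edgeR adjusted p = 0.00389). The nuclear receptor Nr4a3 stood at 22.2 ± 12.4 against 97.8 ± 52.0 CPM (-2.13, SE 0.39, adjusted p = 0.00577), and Spry2, a feedback inhibitor of receptor signalling, fell by 1.99 on the log2 scale (SE 0.38). Of 29 naive and memory genes 12 fell (adjusted p = 0.375 for the list with an estimated correlation). Tcf7, a transcription factor of memory precursors (ENSMUSG00000000782, chromosome 11, 52252371 to 52283014), stood at 74.7 ± 28.6 against 369 ± 415 CPM (-2.30, SE 0.46, adjusted p = 0.00787). Ccr7, a lymph node homing receptor, stood at 402 ± 142 against 833 ± 210 CPM (-1.05), and Slamf6 fell by 1.65 on the log2 scale. The interferon-induced Mx1 (-2.57, SE 0.53, adjusted p = 0.0101) and Ifit2 (-1.22, SE 0.27, adjusted p = 0.0149) fell. Genes that rose included Icos, a costimulatory receptor, from 234 ± 159 to 635 ± 59.3 CPM (1.44, SE 0.38, adjusted p = 0.039), the cytokine Lta (1.46), Il2ra, the alpha chain of the IL-2 receptor, from 956 ± 461 to 1993 ± 208 CPM (1.06), and the glycolytic enzyme Hk2 (1.01). Of the other receptors, Cd160, which is inhibitory, fell by 1.63 and Cd226, which is costimulatory, by 1.69 on the log2 scale. Without the 8 none of these last 6 passed, at 1.30 for Icos, 1.39 for Lta, 1.05 for Il2ra, 1.05 for Hk2, -1.46 for Cd160 and -1.11 for Cd226. The inhibitory receptor list did not pass (median -0.82, preset adjusted p = 0.0727).

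In that comparison 36 of 37 type I interferon genes were negative (median -1.05, 8 called, 16 adjusted over the list alone), 22 of 29 naive and memory genes (-0.82, 12 called, 13 adjusted over the list alone) and 17 of 26 early TCR response genes (-0.77, 7 fell and 2 rose, 14 and 4 adjusted over the list alone). B cell markers were lower as a list by a median of -2.89 (7 called, 16 adjusted over the list alone), macrophage and monocyte markers by -3.75 (5 called) and plasma cell markers by -2.97 (3 called), or by -2.81 with the member at 0 in the TLR7 group set to 3 counts over its 4 libraries. Among them Ighm, the constant region of IgM (ENSMUSG00000076617, chromosome 12, 113418558 to 113422730), fell from 541 ± 133 to 184 ± 63.9 CPM (-1.55, SE 0.25, adjusted p = 0.00389) and Cd74, the MHC class II invariant chain, from 52.9 ± 49.7 to 3.39 ± 1.11 CPM (-3.95). The preset adjusted p was 1.69e-11 for type I interferon, 3.44e-04 for naive and memory, 0.00865 for TCR, 1.14e-06 for B cells, 2.62e-04 for macrophages and 0.00147 for plasma cells. With an estimated correlation the adjusted p = 0.375 for these lists, except 0.523 for macrophages. The OVA group held 1 middle library and TLR7 0, and without the 8 the medians were -1.04, -0.63, -0.46, -2.28, -4.32 and -2.97 in that order. OVA replicate 3, which is not among the 8, held 172 CPM of plasma cell and 221 CPM of macrophage markers. The other OVA libraries held 10.4 to 47.5 and 67.7 to 82.2 CPM, so the values without the 8 do not test that replicate. NF-kB targets (-0.47), the TLR pathway (-0.30, Tlr7 among its 3 called genes) and dendritic cells (-1.46) were lower, and IL-12 and STAT4 (0.67), cytotoxic effectors (0.17), glycolysis (0.15) and ATF4 (0.24) higher, with an adjusted p from 0.375 to 0.707 with an estimated correlation. Without the 8 these stood at -0.28, -0.26 and -1.16, and at 0.78, 0.26, 0.09 and 0.21, and NF-kB targets and glycolysis no longer passed. With the covariate NF-kB targets did not, and without the 5 shallow libraries NF-kB targets (-0.38) and dendritic cells (-1.06) did not.

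There were 527 calls at 72 h for TLR7 against OVA, 60 up and 467 down, 33 and 336 of them by at least 2-fold, and 2721 genes had an unadjusted p under 0.05. The falls included the chemokines Xcl1, at 2.25 ± 3.59 against 121 ± 202 CPM (-5.65), and Ccl4 (ENSMUSG00000018930, chromosome 11, 83662584 to 83664683), at 2.07 ± 0.260 against 71.9 ± 137 CPM (-5.10). Their OVA levels ran from 9.51 to 423 and from 2.62 to 278 CPM. Without the 8 libraries their log2 fold changes were -3.00 and -0.51, and that of Ccl4 no longer passed (adjusted p = 0.238; 0.0331 with all libraries). DESeq2 called 934 genes, the fit without the 8 called 258 (17 up and 241 down), that with the covariate 1923, that on these groups alone 26, and that without the 5 shallow libraries 0. The count was 1370, 308, 278 and 214 without OVA replicates 1 to 4, and 100, 133 and 92 without TLR7 replicates 1, 2 and 4.

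**Figure D4:**
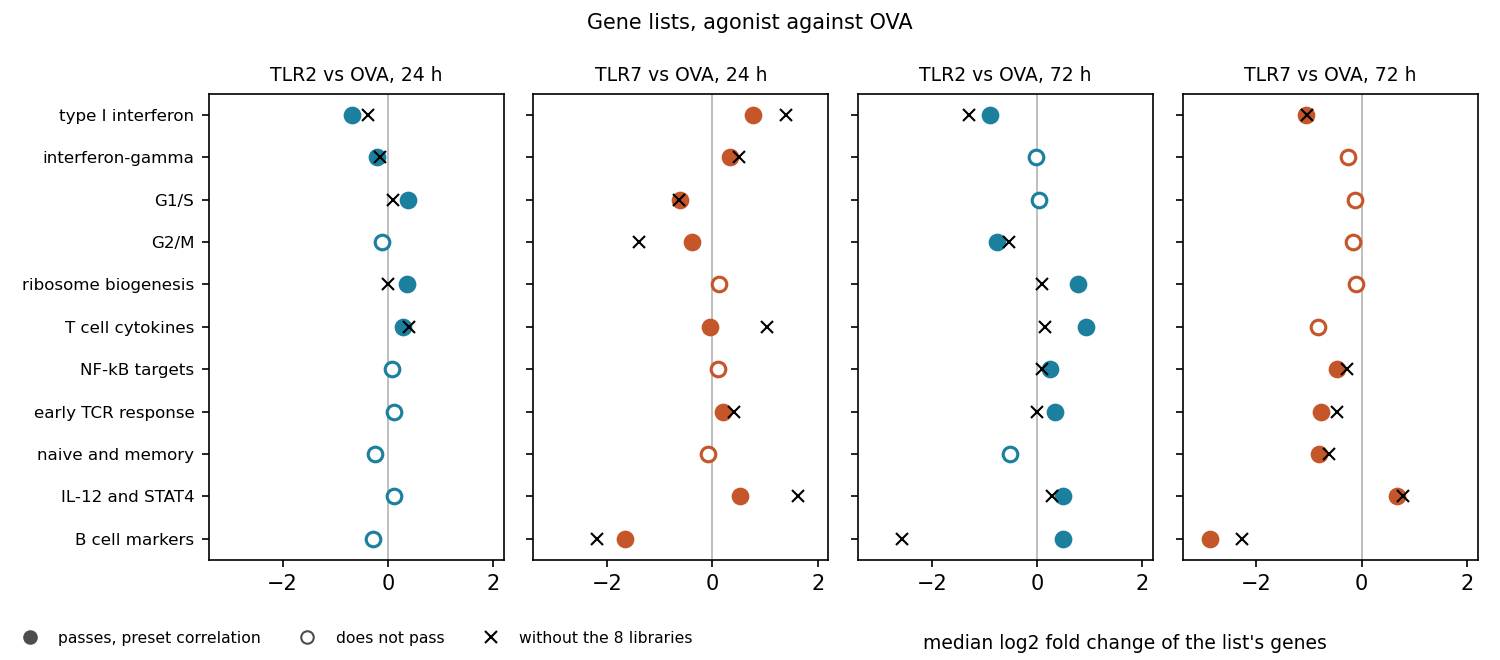
Median log2 fold change against OVA (horizontal axes) of 11 gene lists (rows) with each agonist at 24 h and 72 h. Filled points passed with the preset correlation, open points did not, and crosses give the median of the passing lists without the 8 middle libraries; for TLR7 the type I interferon list lies at 0.77 at 24 h and -1.05 at 72 h.

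With the TLR2 agonist at 72 h no single gene passed against OVA. The type I interferon list was lower by a median of -0.89, with 34 of 37 genes negative and 18 lower adjusted over the list alone (preset adjusted p = 4.42e-23; 0.215 with an estimated correlation). All 32 G2/M genes were negative (median -0.77, preset adjusted p = 2.04e-12), and all 30 ribosome biogenesis genes positive (0.78, preset adjusted p = 1.55e-17), with 0 genes adjusted over the list alone in each and an adjusted p = 0.338 with an estimated correlation for both. T cell cytokines were higher (0.93, 4 genes up adjusted over the list alone; adjusted p = 0.332 with an estimated correlation), as were ER stress genes (0.31; adjusted p = 0.215) and B cell markers (0.50; adjusted p = 0.78). The summed B cell markers were lower instead, at 630 CPM with TLR2 against 739 CPM with OVA. The TLR2 group held 3 middle libraries and OVA 1. Without the 8 the medians were -1.30 for type I interferon, -0.53 for G2/M, 0.09 for ribosome biogenesis, 0.16 for cytokines, 0.42 for ER stress and -2.56 for B cells. IL-12 and STAT4 (0.49), NF-kB targets (0.25), the early TCR response (0.35) and transcription factors (0.16) were higher and CD8 T cell genes (-0.28) lower, with an adjusted p = 0.338 with an estimated correlation; without the 8 they stood at 0.28, 0.10, -0.01, 0.19 and -0.24. Ribosome biogenesis, T cell cytokines, NF-kB targets and the early TCR response no longer passed without the 8, and the medians of the early TCR response and B cells turned. edgeR called 0 genes, with 1693 at an unadjusted p under 0.05, DESeq2 82, the fit with the covariate 764 and that on these groups alone 4. It called 555 without OVA replicate 4 and 5 without OVA replicate 1.

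TLR7 against TLR2 at 72 h gave the most calls between agonists, 699, of which 125 rose and 574 fell (42 and 370 by at least 2-fold). The chemokines Xcl1 (ENSMUSG00000026573, chromosome 1, 164931644 to 164935527), at 2.25 ± 3.59 against 243 ± 168 CPM (n = 4 each; -6.65, SE 1.33, edgeR adjusted p = 0.0154), and Ccl4, at 2.07 ± 0.260 against 155 ± 109 CPM (-6.21, SE 1.37, adjusted p = 0.0196), fell with TLR7. So did Cxcl10, a chemokine induced by interferon, at 0.513 ± 0.197 against 11.5 ± 8.13 CPM (-4.50), Rel, an NF-kB subunit, at 66.3 ± 19.2 against 207 ± 65.4 CPM (-1.64), and the chaperone Hspa5, at 607 ± 81.6 against 1078 ± 81.8 CPM (-0.83, SE 0.20, adjusted p = 0.0256). Cndp2, a dipeptidase, rose from 142 ± 12.4 to 380 ± 70.9 CPM (1.42, SE 0.26, adjusted p = 0.0133), and so did Lta (1.42). Lower as lists were T cell cytokines by a median of -2.05 (8 fell and 2 rose), NF-kB targets by -0.76 (8 called), early TCR response genes by -0.76 (11 called), ribosome biogenesis by -0.87 (3 called), ER stress by -0.41 (3 called) and B cell markers by -3.47 (11 called). Adjusted over the list alone, 10, 17, 14, 17, 12 and 17 genes were lower. With an estimated correlation the adjusted p = 0.432, 0.353, 0.232, 0.588, 0.356 and 0.356 in that order, and no list passed. TLR2 held 3 middle libraries and TLR7 0. Without the 8, which leaves 1 TLR2 library, the medians were -0.28, -0.07, -0.20, 0.26, -0.30 and 0.09. T cell cytokines and B cells then no longer passed, and the medians of ribosome biogenesis and B cells turned. The log2 fold changes without the 8 were -0.97 for Xcl1, -0.53 for Ccl4, -0.89 for Cxcl10 and -0.70 for Rel. They were -0.75 for Hspa5, 1.55 for Cndp2 and 1.23 for Lta.

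Further lists of this comparison passed with the preset correlation only. G2/M (0.51), ATF4 (0.30) and CD8 T cells (0.35) were higher, with an adjusted p = 0.588 with an estimated correlation. Plasma cells (-4.02), macrophages (-2.45), dendritic cells (-1.82) and neutrophils (-5.46) were lower, with an adjusted p of 0.356, 0.588, 0.356 and 0.588. With members at 0 in the TLR7 group set to 3 counts over its libraries, those medians were -3.98, -2.45, -1.22 and -2.56. Without the 8 they were 0.42, 0.23, -0.83 and 0.22, of which dendritic cells alone passed, and G2/M, ATF4 and CD8 T cells stood at 0.36, 0.14 and 0.20, of which G2/M alone passed. With the covariate neutrophils did not pass. Under RLE scaling the calls were 170 up and 423 down, so that 28.7% rose against 17.9% with TMM. DESeq2 called 1521 genes, the fit with the covariate 3756, that on these groups alone 3498, and those without the 8 or without the 5 shallow libraries 0, with 3852 genes at an unadjusted p under 0.05 when all libraries were used. The count was 1, 1667, 70 and 103 without TLR2 replicates 1 to 4, 1 without TLR7 replicate 1, and 0 without TLR7 replicate 2 or 4.

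With OVA alone, 72 h against 24 h gave 2709 calls, 1190 up and 1519 down (570 and 688 by at least 2-fold). Ribosome biogenesis genes fell together, 30 of 30 negative, 29 called and 30 adjusted over the list alone (median -1.34; adjusted p = 0.637 with an estimated correlation). Among them Mybbp1a, a nucleolar protein (ENSMUSG00000040463, chromosome 11, 72441355 to 72451768), stood at 342 ± 253 against 1012 ± 294 CPM (n = 4 each; -1.56, SE 0.40, edgeR adjusted p = 0.0333), and Nop16, a ribosome assembly factor, at 53.1 ± 35.0 against 162 ± 67.4 CPM (-1.61). The G1/S list was lower (median -0.82, 11 called, 21 adjusted over the list alone; adjusted p = 0.637 with an estimated correlation), with the replication helicase subunits Mcm3 and Mcm4 at -1.17 and -1.32, and the G2/M list higher (0.95, 8 called, 19 adjusted over the list alone; adjusted p = 0.637), with the mitotic kinase Aurka at 46.2 ± 9.63 against 20.5 ± 7.31 CPM (1.17). Cd3d, a subunit of the TCR complex, rose from 288 ± 69.2 to 571 ± 104 CPM (0.99), and Cd80, a costimulatory ligand, from 7.35 ± 7.83 to 46.0 ± 18.8 CPM (2.63). Ifng, encoding interferon-gamma, fell from 102 ± 64.7 to 27.4 ± 17.6 CPM (-1.90, SE 0.58, adjusted p = 0.0361). B cell markers were lower as a list (-2.11, 13 called, 17 adjusted over the list alone; adjusted p = 0.637 with an estimated correlation), with Cd79b from 26.0 ± 13.1 to 7.65 ± 3.94 CPM. OVA at 24 h held 2 middle libraries and OVA at 72 h 1, and without the 8 the medians were -2.25 for ribosome biogenesis, -1.48 for G1/S, 1.42 for G2/M and -2.90 for B cells.

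In the same comparison, naive and memory genes (0.66, 8 rose and 1 fell), type I interferon (0.67, 11 rose and 1 fell), hypoxia (0.90), glycolysis (0.50), ATF4 (0.42) and CD8 T cells (0.33) were higher as lists. T cell cytokines (-0.66), NF-kB targets (-0.23), ER stress (-0.46, 9 fell and 3 rose), oxidative phosphorylation (-0.24) and plasma cells (-1.87) were lower. Their adjusted p = 0.637 with an estimated correlation, except 0.738 for glycolysis. Without the 8 they stood at 1.30, 0.95, 2.26, 1.24, 0.72 and 0.61, and at -1.24, -0.47, -0.75, -0.47 and -2.19, and plasma cells no longer passed. With the covariate naive and memory genes, T cell cytokines, NF-kB targets and plasma cells did not, and without the 5 shallow libraries glycolysis (0.33) did not. DESeq2 called 3963 genes, the fit without the 8 called 7673 (4153 up and 3520 down), that with the covariate 6720, that with no filter on low counts 1129, and those on these groups alone or without the 5 shallow libraries 0, with 5826 genes at an unadjusted p under 0.05 in the fit of all libraries. Without OVA 24 h replicates 1, 2 and 4 the count was 4350, 1 and 0, and without OVA 72 h replicates 1 to 4 it was 118, 0, 3 and 4709.

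Whether the TLR7 response differed between the times was tested as the effect at 72 h minus that at 24 h, and 118 genes differed, 16 upward and 102 downward (15 and 92 by at least 2-fold). Aff3, a transcription factor of the AF4 family (ENSMUSG00000037138, chromosome 1, 38177326 to 38664955), differed by -2.11 (SE 0.31, edgeR adjusted p = 0.0118, n = 4 per group), Egr1, an immediate-early factor, by -1.41 (SE 0.23, adjusted p = 0.0165), and Trim25, a ubiquitin ligase of antiviral signalling, by -1.20 (SE 0.20, adjusted p = 0.0165). Fcmr differed by 5.42 (SE 0.96, adjusted p = 0.0171) and H2-DMb2, of the class II peptide loading complex, by 2.32 (SE 0.49, adjusted p = 0.0341). All 37 type I interferon genes were negative, with a median of -1.71, 10 called and 28 adjusted over the list alone (preset adjusted p = 9.49e-25; 0.144 with an estimated correlation). Interferon-gamma (-0.68, 2 called, 12 adjusted over the list alone; 0.144) and the early TCR response (-0.93, 2 called, 11 adjusted over the list alone; 0.144) were lower, the last value being the adjusted p with an estimated correlation. Without the 8 these medians were -2.21, -0.66 and -0.84. NF-kB targets (-0.78), transcription factors (-0.56), naive and memory genes (-0.65), plasma cells (-3.37) and macrophages (-3.11) were also lower and G1/S (0.39), G2/M (0.11) and oxidative phosphorylation (0.14) higher, with an adjusted p from 0.523 to 0.893 with an estimated correlation. Without the 8 they stood at -0.57, -1.04, -0.90, -3.52 and -3.46, and at 0.89, 1.08 and 0.35. Without the 5 shallow libraries the transcription factors (-0.56) did not pass. DESeq2 called 457 genes, RLE scaling left 72, the fit without the 8 called 45, that with the covariate 1108, that on these groups alone 22, and that without the 5 shallow libraries 0. The count fell to 0 without OVA 72 h replicate 2 and to 1 without TLR7 72 h replicate 4, was 28, 19, 65 and 59 without OVA 24 h replicates 2 and 3 and OVA 72 h replicates 3 and 4, and 42, 44, 23, 28 and 30 without TLR7 24 h replicates 1 to 3 and TLR7 72 h replicates 1 and 2. It was 752 without OVA 72 h replicate 1, 247 without TLR7 72 h replicate 3 and 181 without TLR7 24 h replicate 4.

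For the TLR2 response the difference between times gave 0 calls in edgeR, with 919 genes at an unadjusted p under 0.05; DESeq2 called 2 and the fit with the covariate 208. The lists that passed with the preset correlation were type I interferon (-0.35), G1/S (-0.36), G2/M (-0.66), oxidative phosphorylation (-0.09) and erythroid cells (-1.89) downward. Upward they were homing receptors (0.40), glycolysis (0.32), hypoxia (0.60), ATF4 (0.32), p53 (0.23), ribosome biogenesis (0.43), CD4 and regulatory T cells (0.78), B cells (0.97) and platelets (0.77). With an estimated correlation their adjusted p ran from 0.422 to 0.682. The groups of this difference held 2, 0, 1 and 3 middle libraries (OVA and TLR2 at 24 h, OVA and TLR2 at 72 h), and without the 8 only 4 of these 14 lists passed, type I interferon (-0.95), G1/S (-0.75), G2/M (-0.72) and p53 (0.08). Oxidative phosphorylation stood at -0.13, erythroid cells at -2.83, homing receptors at -0.25, glycolysis at -0.03, hypoxia at -0.01, ATF4 at 0.13, ribosome biogenesis at 0.05, CD4 and regulatory T cells at 0.04, B cells at -2.07 and platelets at 0.01. With the covariate platelets did not pass, and without the 5 shallow libraries oxidative phosphorylation (-0.07) and ribosome biogenesis (0.29) did not. The erythroid list turned upward without OVA 72 h replicate 3, and oxidative phosphorylation did so without OVA 24 h replicate 1.

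The agonists were compared for shared effects over genes. At 24 h and at 72 h 0 genes were called in the same direction with both agonists, 0 being also the number for independent lists, since TLR2 had 0 calls in edgeR; DESeq2 gave 12 and 38, and the fit with the covariate 37 and 119. At 72 h 5 genes were shared without OVA replicate 1 and 33 without OVA replicate 4. Log2 fold changes of the agonists correlated across genes, which are not independent replicates, at 0.28 (24 h) and 0.27 (72 h), against 0.06 and 0.04 for 20 simulated pairs of unchanged groups with the same OVA libraries. The covariance was 0.13 at both times, 0.123 and 0.125 above the simulated one. The simulated groups were drawn around the mean of those same OVA libraries, so error in that mean cancels. Their covariance and correlation are therefore near 0 by construction and do not measure what the shared libraries add. With the OVA libraries split between the agonists in 6 ways the mean covariance was -0.105 at both times. It ranged from -0.812 to 0.103 at 24 h and from -0.457 to 0.104 at 72 h, all below 0.13. Part or all of the unsplit value may therefore come from the shared OVA libraries. Signs were the same for 59.2% and 54.3% of genes, against 50.1% and 50.4% in the simulation. With the OVA libraries split the mean share was 50.4% at 24 h (28% to 62.1%) and 44.9% at 72 h (34.4% to 56.8%). These ranges hold the observed shares.

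Because T cells were taken by negative selection, other cells can remain. The summed B cell markers stood at 636 CPM with TLR7 and 1223 CPM with OVA at 24 h, and at 254 and 739 CPM at 72 h. Ighm alone was 371, 583, 689 and 519 CPM of the 468, 663, 1091 and 735 CPM in OVA 72 h replicates 1 to 4. In TLR7 72 h replicates 1 to 4 it was 127, 141, 267 and 202 CPM of 210, 195, 358 and 252 CPM. The sums at 72 h are thus mostly 1 gene, which did not follow other abundant B cell transcripts in 2 of these OVA libraries. Plasma cell sums were 4.3 and 60.8 CPM and macrophage sums 54.5 and 113 CPM with TLR7 and OVA at 72 h. Each of these 4 differences had an exact 2-sided permutation p = 0.0286 with n = 4 each, the smallest that 70 arrangements give, and an adjusted p = 0.114. At 72 h OVA replicate 3 held 172 CPM of plasma and 221 CPM of macrophage markers, against 10.4 to 47.5 and 67.7 to 82.2 CPM in the other OVA libraries, and without it the OVA plasma mean was 23.6 CPM. Of 44 such sums 11 reached that p and 0 passed; with so few arrangements any could pass only if at least 26 reached it. CD4 and regulatory T cell sums stood at 66.8 against 40.9 CPM and NK sums at 115 against 77.2 CPM with TLR7 at 72 h, with exact permutation p of 0.0571 and 0.257.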

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

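The tests of swapped labels, of low depth and of equal sums for the 8 middle libraries, the test of the shared OVA level for the interferon list and both tests for Ighm were chosen after the result was seen.

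The 8 libraries that scored between the others on the first component form the first pattern, for which low depth is argued against, since 0 of the 8 were among the shallow libraries. In all 8, and in 0 of the other 16, a sum of a 24 h and a 72 h library at a weight between 0.35 and 0.65 left under 0.5 of the misfit of the best single library. The single library could not be among the 8, which partly fixes that contrast. The middle score by which the 8 were picked already leaves out a swap of whole libraries between the times, so the sums add no test of it. Weights near the middle partly restate that choice too. The small misfit of the sums was not fixed by it and goes with about equal amounts of both times, though in 5 of the 8 the pair held a library of another agent. Mixed RNA of both times also stays open, with 0 of the 8 holding more genes far above the other 16 libraries than any of those 16 did, a loose bound because OVA 72 h replicate 3 held 308. Whether such a mixture could have arisen before or after sequencing, whether it joined libraries of different agents, or whether the cells were at a time between those in the labels, was not tested, and no biological explanation was tested.

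The type I interferon list, whose TLR7 response was higher at 24 h and lower at 72 h against OVA, is the second pattern (median difference -1.71). Low depth as its whole cause is argued against by -1.87 without the shallow libraries. The level of the shared OVA libraries as the whole cause of the difference is argued against by -1.42 for TLR7 against TLR2 with all libraries. That value uses TLR2 at 72 h, where 3 of 4 libraries were middle ones, and is not given without the 8. Middle libraries may therefore contribute to it. For TLR7 against TLR2 the list passed with the preset correlation at 24 h (median 1.65, and 1.61 without the 8) and not at 72 h. At 72 h TLR2 also stood below OVA (-0.89), so the OVA level as the source of the fall at 72 h stays open. An axis of variation within groups stays open, because the covariate built from it (-1.73) averages the same in every group by construction and so does not decide it; without the 8 middle libraries the median was -2.21. A biological difference in the interferon response between the times also stays open and was not tested. The list's call was lost with an estimated correlation (adjusted p = 0.144). For the count of genes in this difference (118), 6 of 100 splits, the real one included, gave as many. Among these, the splits with 332, 414 and 566 genes kept the real groups at 72 h and changed only those at 24 h. The share thus does not measure chance alone, and chance was not excluded.

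Ighm, lower with the TLR7 agonist at 72 h, is the third pattern. If its level came from B cells alone, their other abundant transcripts would accompany it, but in 2 of the 4 OVA libraries at 72 h Ighm stood at over 10 times the sum of Igkc, Cd74 and H2-Aa (371 against 25.0 CPM and 583 against 20.2 CPM). In the other 2 it stood at 689 against 262 CPM and 519 against 114 CPM. A lower share of all other cells with TLR7 cannot be told apart, because 9 of 11 marker lists had a lower mean and the 2 higher ones overlapped between groups. A change of Ighm within the T cells might remain and was not tested.

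The response to the TLR7 agonist differed between the times for 118 genes by a test of the difference itself (72 h minus 24 h, log2). Among them were Aff3 (-2.11), Egr1 (-1.41), Trim25 (-1.20), Gypc (-1.16) and Setbp1 (-2.76) downward, and Fcmr (5.42), St3gal1 (1.70), Uvrag (1.23), Wdr1 (1.48) and H2-DMb2 (2.32) upward. Without the 8 middle libraries Gypc (-1.04), St3gal1 (1.61), Uvrag (1.00) and Wdr1 (1.27) no longer passed.

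Single libraries stood far from the other 3 of their group in 54 of 534 groups of 4 (8 library measures, 12 marker sums and 34 gene levels), where chance gives about 1 in 20. The ratio given is the gap to the nearest library over the range of the group. The total count was low in OVA 24 h replicate 4 (0.898) and TLR2 24 h replicate 4 (0.953).

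TLR2 72 h replicate 2, the only library of its group outside the middle of the first component, stood apart in that score (0.946), in the share of counts in the top 10 genes (0.934) and in mitochondrial genes (0.865). It also stood apart in the plasma (0.940) and NK (0.947) marker sums and in Ccl4 (0.910), Cd3d (0.860), Cd5 (0.956), Cybb (0.899), Heatr1 (0.857), Ifit2 (0.874), Igha (0.957), Mcm4 (0.858), Mybbp1a (0.953), Pax5 (0.832), Tlr7 (0.841), Utp20 (0.925), Uvrag (0.849), Vldlr (0.988) and Xcl1 (0.912). OVA 72 h replicate 4, the only middle library of its group, stood apart in Ccl4 (0.936), Cd5 (0.954), Heatr1 (0.850) and Mcm4 (0.859).

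TLR2 24 h replicate 2 stood apart in its normalization factor (0.946), its mitochondrial share (0.863), the macrophage (0.848) and erythroid (0.848) sums, Cd5 (0.982), Cd80 (0.877), Mybbp1a (0.926), St3gal1 (0.867) and Utp20 (0.840). OVA 72 h replicate 3 held macrophage (221 CPM, 0.906), erythroid (43.4 CPM, 0.959) and stromal (134 CPM, 0.856) sums above the 67.7 to 82.2, 2 to 3.7 and 33.4 to 47.9 CPM of the others, and Tox2 at a ratio of 1 with 0 counts in the others. OVA 24 h replicate 2 stood apart in the macrophage (0.838), neutrophil (0.842) and erythroid (0.846) sums.

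Other libraries that stood apart were OVA 24 h replicate 4 in the CD8 T cell sum (0.915), OVA 24 h replicate 1 in Egr1 (0.945), and OVA 24 h replicate 3 in Pdcd1 (0.854) and Wdr1 (0.883). So did OVA 72 h replicate 1 in Uvrag (0.919) and Wdr1 (0.840), and TLR2 24 h replicate 4 in Tlr7 (0.834). At 72 h TLR7 replicate 1 stood apart in Nlrc5 (0.854), replicate 3 in the mast cell sum (0.897), Ccr7 (0.837) and Gypc (0.969), and replicate 4 in the top 10 share (0.861).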

How the results depend on the processing

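The fits without the 5 shallow libraries, without the 8 middle libraries and with the first within-group component as a covariate were chosen after the results were seen. Counts of changed genes moved by over 1.5 times as follows, and the cause was not tested. By design, fits on fewer libraries have fewer residual degrees of freedom. The covariate lowers the residual spread by construction, so higher counts with it are no evidence of more changed genes. For OVA at 72 h against 24 h (2709 genes) no filter on low counts gave 1129, the groups compared alone 0, without the 5 gave 0, without the 8 gave 7673 and the covariate 6720. For TLR2 against OVA at 24 h (edgeR 0, with 2211 at an unadjusted p under 0.05) DESeq2 gave 345 and the covariate 1803. At 72 h (edgeR 0, 1693 unadjusted) the replicate block gave 1, the groups alone 4, DESeq2 82 and the covariate 764. For TLR7 against OVA at 24 h (32) the block gave 15, the groups alone 0, DESeq2 243, without the 5 gave 0, without the 8 gave 398 and the covariate 224. At 72 h (527) the groups alone gave 26, DESeq2 934, without the 5 gave 0, without the 8 gave 258 and the covariate 1923.

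For TLR7 against TLR2 at 24 h (180) the groups alone gave 309, DESeq2 1016, without the 5 gave 0 and the covariate 2565. At 72 h (699) the groups alone gave 3498, DESeq2 1521, without the 5 gave 0, without the 8 gave 0 and the covariate 3756. For the difference between times DESeq2 gave 2 and the covariate 208 for TLR2 (0). For TLR7 (118) RLE scaling gave 72, the groups alone 22, DESeq2 457, without the 5 gave 0, without the 8 gave 45 and the covariate 1108. Shared calls (0 at each time in edgeR) were 12 at 24 h and 38 at 72 h in DESeq2, and 37 and 119 with the covariate. Of the lists over all comparisons, 122 passed with the preset correlation, 1 with an estimated correlation and 33 with fry, 30 of these among the 122.

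Leaving out each library in turn gave 0 to 4709 genes for OVA over time, 0 to 546 and 0 to 555 for TLR2 at 24 h and 72 h, 0 to 146 and 92 to 1370 for TLR7, and 0 to 629 and 0 to 1667 for TLR7 against TLR2. The difference between times gave 0 throughout for TLR2 and 0 to 752 for TLR7, and shared calls were 0 throughout at 24 h and 0 to 33 at 72 h. Lists passing numbered 115 to 135, and marker sums passing 0 throughout, which the few arrangements of 4 against 4 libraries nearly fix and which shows no stability.

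Without the 8, these log2 fold changes of TLR7 against TLR2 at 72 h turned: Cd5 0.05, Cybb 1.31, Heatr1 0.03, Igha 1.62, Ighg1 0, Pax5 0.06 and Utp20 0.18. So did the medians of neutrophils (0.22), plasma cells (0.42) and ribosome biogenesis (0.26) in that comparison, of hypoxia (-0.17) and ribosome biogenesis (0.11) at 24 h, of ATF4 (0.01), hypoxia (0.35) and oxidative phosphorylation (-0.11) for TLR2 at 24 h, of B cells for TLR2 at 72 h (-2.56), and of B cells (-2.07) and glycolysis (-0.03) for the TLR2 difference between times. The median alone, not the direction of the test, turned for B cells (0.09) and macrophages (0.23) in TLR7 against TLR2 at 72 h, the early TCR response for TLR2 at 72 h (-0.01), homing receptors (-0.25) and hypoxia (-0.01) for the TLR2 difference, and T cell cytokines for TLR7 at 24 h (1.04). Pdcd1, TLR7 against TLR2 at 24 h (-0.03, not passing), turned to 0.04 with no scaling, 0 with a stricter filter, 0.13 without the 5, 0.18 and 0.07 without TLR2 replicates 1 and 3, and 0.18, 0.21 and 0.04 without TLR7 replicates 1, 2 and 4. With each library left out it ran from -0.76 to 0.21. With each library left out the erythroid list ran from -2.43 to 0.92 for the TLR2 difference between times, turning without OVA 72 h replicate 3. Oxidative phosphorylation ran from -0.16 to 0.06 for that difference, turning without OVA 24 h replicate 1. It ran from -0.21 to 0 for TLR7 at 24 h, reaching 0 without OVA 24 h replicate 2.

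Of 220 results of single genes, 218 kept direction and side of the threshold with DESeq2, 220 with the covariate (which averages the same in every group by construction), 220 with robust empirical Bayes, 207 with RLE scaling, 199 with no scaling, 175 with no filter, 174 with the block, 140 without the 8, 83 on the groups alone and 7 without the 5. With a stricter filter 207 of 214 did, and 816 of 1856 with a library left out. Of 122 list shifts, 118 did with RLE scaling, 110 with the block, 107 without the 5, 106 with the covariate, 83 without the 8 and 30 with fry. The replicate numbers showed no pairing throughout: 21 of 60 same-numbered pairs correlated above 0.1 (-0.616 to 0.525), 0 of 15 pairs of groups did so throughout, and 39 of 120 best matches were to the own number. Middle libraries carry different replicate numbers in different groups, so a weaker pairing may be hidden. Depth limited low genes, since 3 counts correspond to 0.286 CPM in the shallowest library.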

Other observations

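The lists of NK cells, mast cells and basophils, stromal and endothelial cells, and costimulatory receptors passed in no comparison. NK markers stood at a median of -0.94 with TLR7 at 24 h (preset adjusted p = 0.0525) and mast cell and basophil markers at -1.02 (preset adjusted p = 0.0525). The lowest adjusted p was 0.165 for stromal and endothelial cells and 0.0913 for costimulatory receptors, both for a difference between times. Inhibitory receptors were lowest with TLR7 at 72 h, where 7 genes were lower and 1 higher adjusted over the list alone, and stood at -0.07 with TLR7 at 24 h and -0.39 and 0.10 with TLR2 at 24 h and 72 h.

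How often other divisions of the same libraries into groups of 4 call as many genes was a test set before the results were seen. Its counts of splits include the real division. For TLR7 against TLR2 only the real split called as many genes, at 24 h (180 genes, 1 of 35 splits, 56 in the highest other) and at 72 h (699 genes, 1 of 35, 23 in the highest other). A share of 1 of 35 is the smallest possible and was not adjusted over the comparisons. It makes chance less likely and does not exclude it. That says nothing of the middle libraries: 3 were in TLR2 at 72 h and 0 in TLR7, and without the 8 the count at 72 h was 0. It was 1 without TLR2 replicate 1 or TLR7 replicate 1 and 0 without TLR7 replicate 2 or 4, and at 24 h it was 0 without TLR2 replicate 1 or 4. Chance is not excluded for TLR7 against OVA at 24 h (32 genes, 2 of 35 splits, 4982 in the highest other) or 72 h (527 genes, 2 of 35, 534). For OVA over time (2709 genes, 3 of 35, 4806) the test does not decide. The other splits that reached its count, with 3565 and 4806 genes, exchanged only middle libraries between the times. They kept all other OVA libraries with their own time, so they do not measure chance. For the TLR7 difference between times (118 genes, 6 of 100 drawn splits, 1059) chance is not excluded either. Its splits with 332, 414 and 566 genes kept the real groups at 72 h, so that share does not measure chance alone. Where edgeR called 0 genes the test decides nothing, since any split calls as many: 35 of 35 for TLR2 at 24 h (highest 3; 2211 genes at an unadjusted p under 0.05, 345 by DESeq2) and at 72 h (highest 2404; 1693 and 82), and 100 of 100 for the TLR2 difference between times (highest 734; 919 and 2). Splits that call several times the real count, as for TLR7 at 24 h, point to a structure of the samples. There the split with 4982 genes set OVA replicates 1 and 3 and TLR7 replicates 3 and 4 against the rest. For TLR2 at 72 h the split with 2404 genes set OVA replicate 4 and TLR2 replicates 1, 3 and 4 against the rest. Both divide the middle libraries from the others.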
